A study of Homo sapiens with 80 samples.

How the data were processed

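RNA from blood cell fractions of smoking and nonsmoking adults was measured on 80 Affymetrix arrays. Per the labels' protocols, the mononuclear layer of whole blood was taken by density gradient centrifugation, the cells were purified with antibody-coated magnetic beads, and total RNA was amplified with the Nugen WT-Ovation Pico system and labelled with biotin. The fractions are named CD4+, CD8+, CD14+ and CD56+ after the antibody. The labels give smoking as yes or no, with no amount or duration. The titles carry a donor code, from which 23 donors were counted. Of these, 19 gave all 4 fractions (9 smokers and 10 nonsmokers) and 4 gave CD56+ cells alone.

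The deposited table holds log2 values summarised per transcript cluster. That unit was inferred from the range of the values, since how the authors normalized them is not given in the sources used here. The replicate numbers in the titles form 3 runs, called title series A (40 arrays), B (36 arrays) and C (4 arrays) below. Their deposited values lie on different scales. Array medians were 5.45 to 5.66 in series A, 4.68 to 5.10 in series B and 5.41 to 5.51 in series C. The highest value of an array was 14.05 to 14.38 in series A, 19.78 to 19.91 in series B and 19.75 to 19.87 in series C. Levels are therefore given per series, a pooled log2 difference averages over unlike scales, and a fold computed from it would be approximate. The median correlation of an array with the other arrays of its fraction and series was 0.982 to 0.992 in A and 0.954 to 0.983 in B. Arrays have no read depth, so their number limits the precision.

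Of 70523 measured features, 67528 were transcript clusters, and 2995 control or exon features were left out. The platform annotation gave 1 gene symbol to 23781 transcript clusters and several to 1543, while 42204 were not listed and stayed unnamed. Symbols were updated by Entrez identifier through a RefSeq table for 21437 of them. After 79 clusters of Y-linked genes, XIST and TSIX were left out, 23702 clusters of 22388 genes remained. No gene is named from a cluster with several symbols, and AHRR, which has no cluster of its own, was not analysed here. No coordinates are given, because the files do not state a genome build.

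The smoking comparison was made in each fraction with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with title series as a term. A gene was represented by its probe set with the highest mean and was tested when that mean lay above the median of all transcript clusters in the fraction. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. The mean of the 4 fractions was compared with 1 value per donor. Whether a smoking difference varied between fractions was tested with the moderated F of limma over the 76 arrays of donors with all 4 fractions, with each pair of fractions as a contrast. Genes of a fraction had to exceed each other fraction by over 1 log2 unit at adjusted p under 0.05. Gene lists (31, of which 10 were cell type markers) were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation. Marker means were compared by exact permutation of smoking within title series. Tests, lists, markers and the rule for naming genes were set before the data were examined.

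The rule named, in each smoking comparison, up to 10 genes past the threshold with the largest rise and fall, or the 5 with the smallest p in a direction where fewer than 5 passed. It added GPR15 and LRRN3 in every fraction, members of the smoking-associated list at unadjusted p under 0.05, and 2 to 4 members of each list described. It also took the 10 genes with the smallest p in the test between fractions and the 5 leading genes of each fraction. HLA, KIR and receptor segment genes stayed in the tests but are not named.

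Samples of a donor were checked for pairing, as the titles share donor codes. Over all genes, the deviations of a donor's arrays from their group and series means correlated with a median r of 0.154 to 0.279 between pairs of fractions. With the donor as a random replicate block, the within-donor correlation was 0.142 in the smoking fit of all arrays and 0.137 in the test between fractions, where 11 genes passed instead of 3. A second check used 100 genes whose levels varied most between donors, chosen in the other series. Of 76 arrays, 2 matched another donor by a margin in r over 0.3, both of them CD8+. Each matched the donor of the other, and those donors came from opposite smoking groups. The best match of 2 further arrays was also another donor, by a margin of at most 0.14. Labels were kept as deposited.

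The procedures were tested on simulated data with known changes. The simulated values were normal and independent between genes and arrays, with 1 spread per gene and no array that stands apart. Many genes were also changed at once (67 by 0.5, 67 by 1 and 66 by 2 log2 units), which eases the Benjamini-Hochberg threshold. Recovery in the real data, where genes vary together and the series differ in spread, can therefore be lower. The real fits of single fractions called 0 or 1 gene. There LRRN3 in CD4+ cells (1.27 log2 units) and GZMB in CD8+ cells (1.45) did not pass, so the shares below overstate the power. Changes of 1 log2 unit were recovered for 98.5% of genes in each fraction and for 97.0% in the test between fractions. Changes of 0.5 log2 units were recovered for 76.1% of genes in CD4+ cells, 86.6% in CD8+, 80.6% in CD14+ and 89.6% in CD56+ cells, and for 64.2% in the test between fractions. Alternatives to the covariates, array weights, variance prior, filter, probe set rule, normalization, series, donor block and marker adjustment were computed for the genes of each fraction, and a smaller set of them for the other results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.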

Results

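Smoking and nonsmoking adults were compared in CD4+ T cells, CD8+ T cells, CD14+ monocytes and CD56+ cells, which include natural killer (NK) cells, from peripheral blood. The share of NK cells in the CD56+ fraction was not measured. The CD4+, CD8+ and CD14+ fractions each had 9 smokers and 10 nonsmokers, and the CD56+ fraction had 12 smokers and 11 nonsmokers. Every array held 1 fraction of 1 donor, with no repeat hybridisation. Series A had 5 smokers and 5 nonsmokers per fraction, series B had 4 and 5, and series C had 3 and 1 in CD56+ cells alone.

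Genes above 1 log2 unit over each other fraction were counted, and the 5 leading genes of each fraction included known markers of its cell type. CD4+ cells had 21 genes above each other fraction, led by TSHZ2 (smallest difference 2.48 log2 units), the skin-homing receptor CCR4 (1.96), the interleukin-2 receptor chain IL2RA (1.88), CTLA4 (1.74) and GPR183 (1.68). CD8+ cells had 10, led by LINC02446 (3.24), the coreceptor chain CD8B (2.93) and its pseudogene CD8BP (2.60), a near-identical copy whose signal cannot be separated from it. NT5E (1.96), an ectoenzyme that makes adenosine, and NELL2 (1.46) followed. CD14+ cells had 870, led by the alarmin S100A12 (7.87), CYP1B1 (6.97), the lipopolysaccharide coreceptor CD14 (6.93), VCAN (6.83) and the oxidase subunit CYBB (6.37). CD56+ cells had 128, led by the NK receptors KLRF1 (4.84) and KLRC1 (3.64), SH2D1B (4.74), IL18RAP (3.52) and NCAM1, which encodes CD56 (3.39). The CD56+ fraction also held monocyte and T cell transcripts, the CD4+ fraction monocyte transcripts, and the CD8+ fraction transcripts of the NK receptor gene KLRF1. The monocyte lysozyme gene LYZ averaged 11.31 ± 0.75 (SD, n = 10) in CD56+ cells of series A, against 12.73 ± 0.083 in CD14+, 9.60 ± 1.27 in CD4+ and 5.66 ± 0.86 in CD8+ cells. In series B it averaged 18.30, 19.15, 16.83 and 9.09 in the same order (n = 9). CD3E, a subunit of the T cell receptor complex, averaged 9.09 ± 0.47 in CD56+ and 10.11 ± 0.10 in CD4+ cells of series A. KLRF1 averaged 7.38 ± 1.23 in CD8+, 4.705 ± 1.44 in CD4+ and 10.67 ± 0.37 in CD56+ cells of series A. In series B it averaged 9.75, 5.20 and 16.29 in the same order.

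GPR15, a chemoattractant receptor that guides T cells to the large intestine and the skin, rose in CD4+ cells of smokers. Its probe set (TC03000494.hg.1) was higher by 3.74 ± 0.49 log2 units (SE, adjusted p = 0.00471), and 9 of 9 smokers lay above the median of the nonsmokers of their series. In series A it averaged 9.19 ± 0.73 (SD, n = 5) in smokers and 6.12 ± 0.55 (n = 5) in nonsmokers. In series B it averaged 11.43 ± 0.94 (n = 4) and 6.93 ± 1.79 (n = 5). LRRN3, a leucine-rich repeat protein of naive and central memory T cells, was higher by 1.27 ± 0.29 in 9 of 9 smokers, by 1.54 in series A and 0.98 in series B, without passing (adjusted p = 0.998). With the donor as a block LRRN3 passed (adjusted p = 0.0459). RCBTB2 (0.34), CHMP2A (0.26), LCMT1-AS2 (0.31) and the claudin-domain gene CLDND1 (0.32) were higher at an unadjusted p under 0.05. The adenylate kinase AK5 (-0.57), ZSWIM5 (-0.33), the nuclear receptor corepressor NRIP1 (-0.31), RPL23AP53 (-0.25) and TXLNG (-0.19) were lower in the same way.

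GPR15 was the 1 gene of 15098 that passed in CD4+ cells, and 626 had an unadjusted p under 0.05 where chance gives 755. That count depended on the fit, from 74 without the series term to 1199 with the marker covariate. Without the least correlated array it was 979, 185 higher and 794 lower, instead of 194 and 432. The limma fit of series B alone called 0 genes, with 915 at an unadjusted p under 0.05. Of all genes tested, 43.3% had the same sign in series A and B.

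In the lymphocyte homing list, of which GPR15 is a member, 13 of 14 measured genes were higher in CD4+ cells (adjusted p = 8.04e-06 by camera), among them the mucosal receptor CCR6 (0.36) and the skin receptor CCR10 (0.30). With an estimated correlation the adjusted p was 0.0732, and 1 member, GPR15, passed adjusted over the list alone, as over all genes. Without GPR15 the mean of the list was 0.17 instead of 0.42 (adjusted p = 0.000819, and 0.211 with an estimated correlation). Type I interferon genes were higher in 18 of 19 (adjusted p = 8.04e-06, and 0.401 with an estimated correlation), with IFIT2 at 0.28 and OASL at 0.22, but their adjusted p in series B alone was 0.217. Of the genes that other cohorts tied to smoking in blood, 13 of 16 were higher (adjusted p = 9.95e-05, and 0.0732 with an estimated correlation). Their mean difference was 0.34 and their median 0.047, and the list was not tested without GPR15. GPR15 and LRRN3 passed adjusted over the list alone, 2 genes against 1 over all genes. Monocyte markers were higher in 12 of 12 (adjusted p = 1.33e-05, and 0.401 with an estimated correlation), such as the beta-glucan receptor CLEC7A (0.54) and the calgranulin S100A8 (0.40), but their mean did not pass by exact permutation (0.45, adjusted p = 0.87), nor did any other marker mean. Naive and central memory T cell genes were lower in 16 of 17 (adjusted p = 0.000244, and 0.401 with an estimated correlation), LRRN3 being the exception. The transcription factor BACH2 (-0.56) and NELL2 (-0.63) were among them, and adjusted over the list alone LRRN3 and BACH2 passed in opposite directions, against 0 of the list over all genes. The naive and central memory list pointed down in series B alone (adjusted p = 0.000485) and up in series A alone (0.819). T cell markers were lower in 10 of 11 (adjusted p = 0.0441, and 0.665 with an estimated correlation), and their mean (-0.13) was higher by 0.10 in series A and lower in series B (-0.38). Regulatory T cell genes were higher in 9 of 12 (adjusted p = 0.00408, and 0.116 with an estimated correlation), with FOXP3 at 0.17 and IL2RA at 0.45. Antioxidant genes induced by NRF2 were higher in 11 of 14 (adjusted p = 0.0101, and 0.401 with an estimated correlation), with the quinone reductase NQO1 at 0.16 and the heme oxygenase HMOX1 at 0.15. The list of aryl hydrocarbon receptor targets, which tobacco smoke compounds induce, also holds regulators such as AHR. It was higher in 7 of 7 (adjusted p = 0.0441, and 0.211 with an estimated correlation), at a median of 0.031. By camera it did not pass in CD8+ (adjusted p = 0.209), CD14+ (0.759) or CD56+ cells (0.967). Ribosomal protein genes were lower in 12 of 16 (adjusted p = 0.0116, and 0.523 with an estimated correlation), with RPS3 at -0.12 and RPL27 at -0.16, though RPL27 was 0.073 higher in series A. In all, 13 of 31 lists passed, 10 higher and 3 lower, and 0 with an estimated correlation. Without the least correlated array 8 passed, 7 higher and 1 lower.

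**Figure D1:**
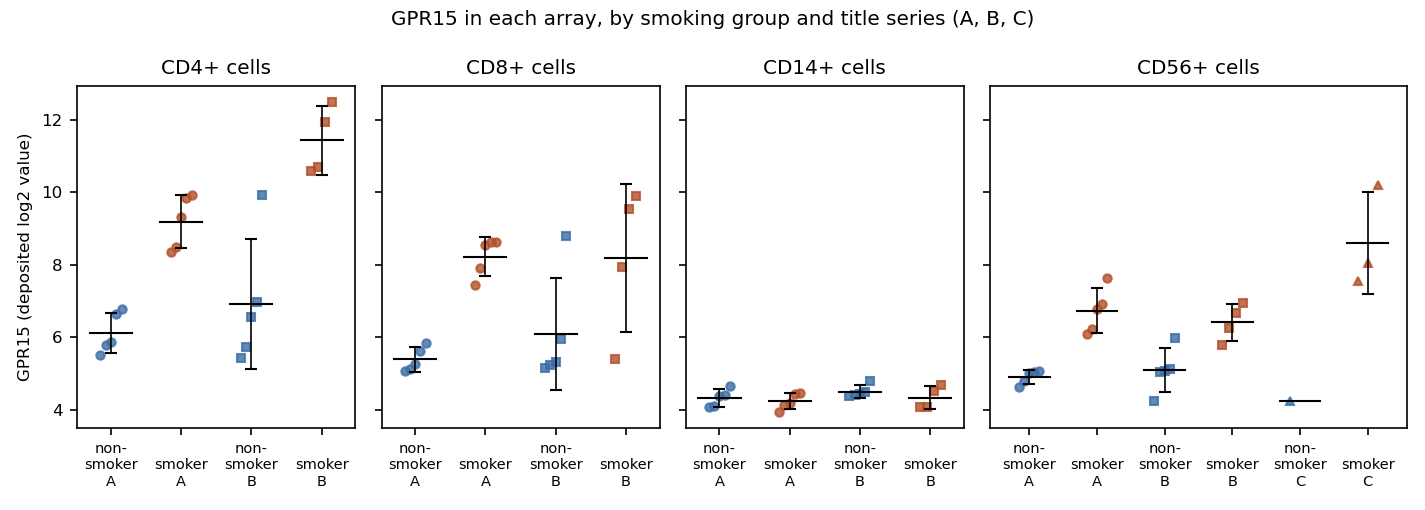
Deposited log2 value of GPR15 in every array, by cell fraction, labelled smoking group and title series. Points are donors, horizontal lines are means and bars are SD. Smokers average 9.19 against 6.12 in CD4+ cells of series A, and both groups lie near 4.3 in CD14+ cells (4.23 and 4.33 in series A).

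In CD8+ cells GPR15 was again higher in labelled smokers, by 2.49 ± 0.52 log2 units in 9 of 9, but did not pass (adjusted p = 0.765). Labels limit this comparison, because 2 CD8+ arrays from opposite groups matched the donor of the other. Without those 2 arrays GPR15 was higher by 3.19 and passed (adjusted p = 1.58e-05), and with the donor as a block it also passed (adjusted p = 0.00144). Its mean was 8.23 ± 0.54 (SD, n = 5) in smokers and 5.39 ± 0.34 (n = 5) in nonsmokers of series A. In series B, which holds both arrays, it was 8.19 ± 2.05 (n = 4) and 6.09 ± 1.54 (n = 5). The granule protease GZMB was higher by 1.45 ± 0.35, by 0.52 in series A and by 2.50 in series B. The lysophosphatidic acid receptor LPAR6 (0.48 ± 0.099), the vesicle protein SYT11 (0.84 ± 0.19), the lysosome trafficking regulator LYST (0.88 ± 0.21) and CLDND1 (0.42 ± 0.18) were also higher without passing. The lymphocyte transcription factor SOX4 (-0.25), the GTPase regulator ARHGAP32 (-0.29), ANKRD34A (-0.21) and the noncoding MIR4654 (-0.43) and NUCB1-AS1 (-0.34) were lower without passing. LRRN3 differed by 0.18 ± 0.37, higher by 0.98 in series A and lower in series B (-0.72).

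By limma 0 of 15092 genes passed in CD8+ cells, and 949 had an unadjusted p under 0.05 (chance gives 755). With the donor as a block 9 passed, in series A alone 1 (GPR15), and in series B alone 27, of which 25 were higher.

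Cytotoxic effector genes were the list with the smallest adjusted p in CD8+ cells, higher in 21 of 21 (adjusted p = 2.21e-13, and 0.457 with an estimated correlation). The cystatin CST7 (1.002) and the pore-forming protein PRF1 (1.09) were among them with GZMB and PRSS23 (0.34), and 8 members passed adjusted over the list alone against 0 over all genes. The adjusted p was 4.32e-18 in series B alone and 0.503 in series A alone, where GZMB, CST7 and PRF1 were higher by 0.52, 0.065 and 0.27. Without the 2 arrays in question its adjusted p was 4.52e-10. NK markers were higher in 11 of 12 (adjusted p = 0.000421, and 0.457 with an estimated correlation), with MLC1 at 0.18 and the activating receptor NCR1 at 0.40. NCR1 was lower in series A (-0.081) and higher in series B (0.95), and the NK marker mean did not pass by exact permutation (0.41, adjusted p = 0.153), nor did any other marker mean. The NK marker mean differed by -0.049 in series A and by 0.92 in series B, where the cytotoxic list passed. Whether NK content lies behind that list was not tested. Among NK receptors 11 of 15 were higher (adjusted p = 0.0169, and 0.457 with an estimated correlation), with CD244 at 0.50, while KLRB1, a receptor of innate-like T cells, was the other way at -1.01. Naive and central memory genes were lower in 15 of 17 (adjusted p = 1.08e-05, and 0.457 with an estimated correlation), with BACH2 at -0.52 and MYC at -0.39. MYC was 0.13 higher in series A, where the list pointed up (adjusted p = 0.0539). Interferon genes were higher in 16 of 18 (adjusted p = 5.81e-05, and 0.457 with an estimated correlation), with the ubiquitin ligase HERC5 at 0.38 and IFIT2 at 0.25. Homing genes were higher in 9 of 13 (adjusted p = 0.00891, and 0.457 with an estimated correlation), with CCR4 at 0.83 and the integrin chain ITGA4 at 0.51, but not without GPR15 (adjusted p = 0.0663). B cell markers were lower in 10 of 10 (adjusted p = 0.0119, and 0.533 with an estimated correlation), with the kinase BLK at -0.29 and CD79A at -0.45. That call rested on 1 nonsmoker array, whose B cell marker mean lay 2.57 above the middle of its series (next 0.171). Without it the list was 0.055 higher (adjusted p = 0.657), and the marker mean with it (-0.26) had an exact permutation p of 0.741. The smoking-associated list did not pass (9 of 16 higher, adjusted p = 0.415), and GPR15 alone passed adjusted over the list alone. In all 9 lists passed, 6 higher and 3 lower, and 0 with an estimated correlation. Of the 9, 3 passed in the same direction in series A alone, where 5 pointed the opposite way. In series B alone 6 of them passed in the same direction.

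GPR15 lay under the signal filter in CD14+ monocytes, at 4.23 in smokers and 4.33 in nonsmokers of series A, and other genes led there. SASH1, a scaffold protein of Toll-like receptor 4 signalling, was higher by 0.93 ± 0.17 log2 units in 8 of 9 smokers without passing in the pooled fit (adjusted p = 0.104). SASH1 averaged 7.81 ± 0.17 (SD, n = 5) against 6.71 ± 0.34 (n = 5) in series A and 6.92 ± 0.39 (n = 4) against 6.19 ± 0.54 (n = 5) in series B. It passed in series A alone (adjusted p = 0.0237) and with the donor as a block (adjusted p = 2.85e-07). The desmosomal cadherin DSC2 (1.03 ± 0.31), the lysosomal fucosidase FUCA1 (0.66 ± 0.21), the insulin signalling gene PID1 (0.50 ± 0.15), the Ral regulator RGL1 (0.48 ± 0.12) and the semaphorin SEMA6B (0.33 ± 0.11) were each higher in 8 of 9 smokers without passing. FBXO8 (0.37), the pseudokinase STRADB (0.38), the mitochondrial esterase ABHD10 (0.41) and HCP5 (0.46), a noncoding gene of the HLA region, were higher in 9 of 9. The dendritic cell chemokine receptor XCR1 (-0.26) and the noncoding SUCLA2-AS1 (-0.21), LINC00504 (-0.24), RNA5SP501 (-0.37) and MIR1228 (-0.30) were lower without passing.

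By limma 0 of 15266 genes passed in CD14+ cells, but 2786 had an unadjusted p under 0.05 (chance gives 763), 1912 higher and 874 lower. The split depended on the processing, with 3894 higher and 62 lower after centring each array on its median, 1849 and 230 after quantile normalization, 809 and 673 after cyclic loess within series, and 2385 and 2709 with array weights. With the marker covariate 1127 genes had an unadjusted p under 0.05, 772 higher and 355 lower. Of all genes tested, 70.7% had the same sign in series A and B. With array weights 611 genes passed, 356 higher and 255 lower, and with the donor as a block 568, 510 higher and 58 lower. The block fit takes 1 residual spread for all fractions.

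The smoking-associated list was higher in 13 of 17 genes in CD14+ cells (adjusted p = 0.0211, and 0.272 with an estimated correlation), with adjusted p = 0.0112 in series A and 0.0342 in series B. Adjusted over the list alone 6 passed, SASH1, RGL1, DSC2, PID1, FUCA1 and SEMA6B, against 0 over all genes. Interferon genes were higher in 19 of 20 (adjusted p = 0.00465, and 0.771 with an estimated correlation), with MX2 at 0.52 and OASL at 0.39, with an adjusted p of 2.81e-08 in series A alone and 0.415 in series B alone. Monocyte markers were higher in 13 of 13 (adjusted p = 0.028, and 0.771 with an estimated correlation), including CPVL (0.59), CD14 (0.55) and the growth factor receptor CSF1R (0.38). In 1 nonsmoker their mean lay at -1.03 from the middle of its series (next -0.323). The mean difference of 0.27 (exact permutation p = 0.015, adjusted p = 0.135) was 0.17 without that array, replicate 8, and 0 marker means passed by exact permutation. Classical monocyte genes were higher in 12 of 12 (adjusted p = 0.0391, and 0.771 with an estimated correlation), with the chemokine receptor CCR2 at 0.65 and THBS1 at 2.17, of which 0.063 in series A. Cytotoxic genes were lower in 12 of 16 (adjusted p = 0.0324, and 0.771 with an estimated correlation), with GNLY at -0.19, the 1 member past adjusted over the list alone, and ZNF683 at -0.12. B cell markers were lower in 8 of 9 (adjusted p = 0.0324, and 0.771 with an estimated correlation), with TCL1A at -0.16 and FCRL1 at -0.13. Without nonsmoker replicate 8, the least correlated array, neither the cytotoxic list (adjusted p = 0.054) nor the B cell list (0.0505) passed, and 3 lists passed, 3 higher and 0 lower. The differences stayed similar in size, with a cytotoxic mean of -0.060 before and -0.047 after, and a B cell mean of -0.085 before and -0.071 after. In series A alone 8 lists passed, 8 higher and 0 lower, and in series B alone 5, 1 higher and 4 lower. Dendritic cell genes did not pass as a list (adjusted p = 0.839), with 5 of 10 higher. Adjusted over the list alone the lectin CLEC10A (0.77), the lipid antigen presenter CD1C (0.40) and TCF4 (0.21) were higher and XCR1 lower, against 0 over all genes. In all 7 of 30 lists passed, 4 higher and 3 lower, and 0 with an estimated correlation.

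**Figure D2:**
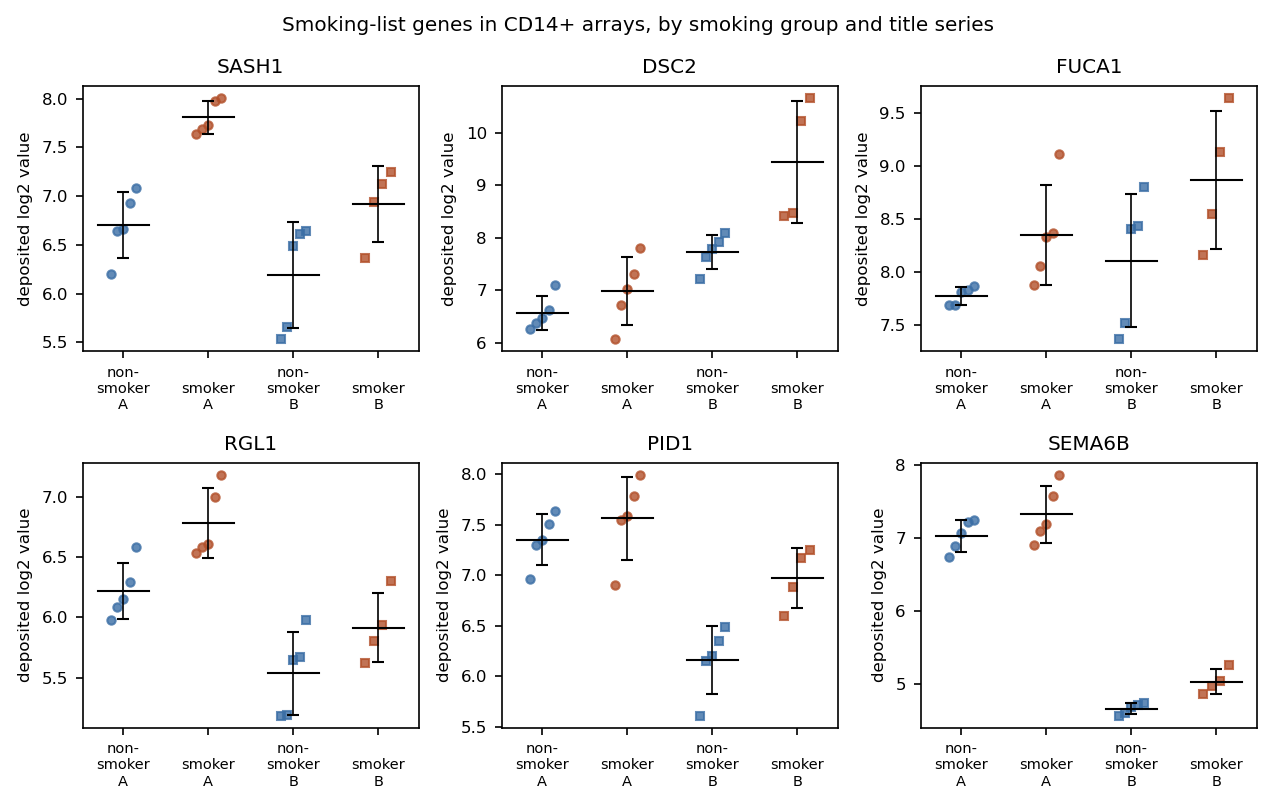
Deposited log2 values of the 6 genes of the smoking-associated list with an unadjusted p under 0.05 in CD14+ cells, by smoking group and title series. Points are donors, horizontal lines are means and bars are SD. SASH1 averages 7.81 against 6.71 in series A and 6.92 against 6.19 in series B, and none of the 6 passed over all genes.

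In CD56+ cells GPR15 was higher by 1.97 ± 0.34 log2 units in 12 of 12 smokers without passing over all genes (adjusted p = 0.0922). It averaged 6.73 ± 0.62 (SD, n = 5) against 4.90 ± 0.19 (n = 5) in series A, 6.42 ± 0.51 (n = 4) against 5.10 ± 0.62 (n = 5) in series B, and 8.60 ± 1.42 (n = 3) against 4.26 in the single nonsmoker of series C. Without series C it passed at a difference of 1.59 (adjusted p = 0.0131), and with the donor as a block at 1.97 (adjusted p = 0.0183). The RNA-degrading regulator ZC3H12D was higher by 0.20 ± 0.035 in 12 of 12 (adjusted p = 0.0922). LPAR6 (0.40 ± 0.080), the inhibitory receptor CD101 (0.40 ± 0.081), TTN-AS1 (0.29), LRRN3 (0.58), the transcription factor LEF1 (0.54), CLDND1 (0.25), PID1 (0.18) and the thrombin receptor F2RL3 (0.10) were also higher without passing. The coactivator NCOA1 (-0.36), FHL3 (-0.31), the kinase STK26 (-0.29), TMEM223 (-0.25) and the phosphatase subunit PPP2CA (-0.20) were lower without passing. By limma 0 of 15010 genes passed, 1141 had an unadjusted p under 0.05 (chance gives 750), and with the donor as a block 8 passed.

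In CD56+ cells, 1 marker mean passed by exact permutation and several cell type lists passed camera at the preset correlation alone. NK markers were lower in 11 of 12 (adjusted p = 4.04e-07, and 0.153 with an estimated correlation), with MLC1 at -0.46, NCR1 at -0.47 and CD160 at -0.68. NK receptors were lower in 12 of 15 (adjusted p = 7.37e-06, and 0.153 with an estimated correlation), with KLRB1 at -0.85. Monocyte markers were higher in 13 of 13 (adjusted p = 4.04e-07, and 0.238 with an estimated correlation), with CSF1R at 0.41, past adjusted over the list alone, and CLEC7A at 0.76. Nonclassical monocyte genes were higher in 11 of 13 (adjusted p = 0.0138, and 0.331 with an estimated correlation), and 3 passed adjusted over the list alone, with LILRB1 at 0.39 and MS4A7 at 0.61. CD4+ T cell markers were higher in 4 of 4 (adjusted p = 0.000748, and 0.0502 with an estimated correlation), and 3 passed adjusted over the list alone, the costimulator ICOS (0.76), CCR4 (0.60) and CD4 (0.59). Their mean was higher by 0.50 (within-group SD 0.28, exact permutation p = 0.000362, adjusted p = 0.00326 over 9 marker sets), by 0.29 in series A and 0.41 in series B. CD4 does not separate T cells from monocytes here, as it averaged 10.22 in CD14+ and 9.64 in CD4+ cells of series A, and 12.61 and 11.41 in series B. T cell markers were higher in 11 of 11 (adjusted p = 0.00331, and 0.378 with an estimated correlation), with UBASH3A at 0.33 and TRAT1 at 0.70. The marker means of NK cells (-0.41, adjusted p = 0.0886 by exact permutation) and monocytes (0.57, adjusted p = 0.104 by exact permutation) did not pass. The smoking-associated list was higher in 15 of 17 (adjusted p = 5.19e-05) and was the 1 list that also passed with an estimated correlation (0.0464). Its mean difference was 0.23 and its median 0.055, and it was not tested without GPR15. GPR15, LRRN3 and PID1 passed adjusted over the list alone, against 0 over all genes. Homing genes were higher in 11 of 13 (adjusted p = 0.000893, and 0.0554 with an estimated correlation), and 4 passed adjusted over the list alone, including ITGA4 (0.52) and ITGB1 (0.41), which differed by 1.03 and 0.78 in series B and by 0.021 and -0.0040 in series A. Without GPR15 the adjusted p of the list was 0.0113 (0.153 with an estimated correlation). Interferon genes were higher in 19 of 19 (adjusted p = 0.00146, and 0.598 with an estimated correlation), with MX2 at 0.59 and IFI44L at 1.24. Their mean of 0.49 was 0.23 without series C, which has a single nonsmoker. In series A alone the list was higher (adjusted p = 7.61e-06), and in series B alone it pointed down (0.637). Cytotoxic genes were lower in 17 of 21 (adjusted p = 0.00194, and 0.397 with an estimated correlation), with PRSS23 at -0.40 and ZNF683 the other way at 0.29. In all 18 of 30 lists passed, 13 higher and 5 lower. In series A alone 7 higher and 4 lower passed, and in series B alone 0 higher and 5 lower. With the marker covariate 15 passed, 3 higher and 12 lower, and 4 of the 18 lists pointed the opposite way, of which 2 passed.

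Averaged over the 4 fractions of a donor, 5 genes rose in smokers and 0 fell, each with 9 of 9 smokers above the nonsmoker median of their series. GPR15 rose by 1.92 ± 0.22 log2 units (adjusted p = 0.00057), by 1.91 in series A and 1.94 in series B. RCBTB2 (TC13000656.hg.1), a gene of the chromosome condensation regulator family, rose by 0.36 ± 0.050 (adjusted p = 0.00788), by 0.35 and 0.36. CRYBG3 (TC03000480.hg.1), a protein with crystallin domains, rose by 0.38 ± 0.062 (adjusted p = 0.0311), by 0.25 and 0.53. The choline and heme transporter gene FLVCR2 (TC14002303.hg.1) rose by 0.31 ± 0.053 (adjusted p = 0.0479), by 0.26 and 0.36. LILRA2 (TC19002652.hg.1), an activating receptor of myeloid cells, rose by 0.21 ± 0.037 (adjusted p = 0.0479), by 0.22 and 0.21. KLRB1 had the smallest p among lower genes without passing (-0.63 ± 0.14, adjusted p = 0.168, 0 of 9 smokers above), followed by the adaptor APBA2 (-0.29), the IgM receptor FCMR (-0.28), RNY4P30 (-0.27) and NUCB1-AS1 (-0.15). The fit tested 15926 genes by limma, and 1069 had an unadjusted p under 0.05 (chance gives 796). GPR15 passed with each alternative run except series B alone, while each of the other 4 genes was lost under at least 1 further alternative.

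The smoking-associated list, of which GPR15 is a member, had 17 of 19 genes higher in the donor means (adjusted p = 6.51e-10, and 0.00355 with an estimated correlation), the 1 list of 11 that passed both ways. Its mean difference was 0.22 and its median 0.070, and it was not tested without GPR15. Adjusted over the list alone 8 passed, including SASH1 (0.31), CLDND1 (0.27) and RGL1 (0.19), against 1 over all genes. FUCA1 (0.22), DSC2 (0.32), PID1 (0.19), LRRN3 (0.47), SEMA6B (0.11) and STAB1 (0.070) of this list also had an unadjusted p under 0.05. Monocyte markers were higher in 13 of 13 (adjusted p = 1.92e-11, and 0.104 with an estimated correlation), and 12 passed adjusted over the list alone, including CLEC7A (0.42), CSF1R (0.28) and S100A8 (0.24). Classical monocyte genes were higher in 12 of 12 (adjusted p = 8.03e-08, and 0.104 with an estimated correlation), and 7 passed adjusted over the list alone, including VCAN (0.72) and CSF3R (0.22). Interferon genes were higher in 19 of 20 (adjusted p = 1.2e-06, and 0.464 with an estimated correlation), with OASL at 0.28 and IFIT2 at 0.31. Homing genes were higher in 12 of 15 (adjusted p = 0.000422, and 0.104 with an estimated correlation), and 4 passed adjusted over the list alone, GPR15, ITGB7 (0.18), ITGA4 (0.40) and ITGB1 (0.32), against 1 over all genes. ITGB7 and ITGA4 form the gut-homing integrin. Without GPR15 the adjusted p of the list was 0.0155 (0.371 with an estimated correlation). NRF2-induced genes were higher in 12 of 15 (adjusted p = 0.0122, and 0.464 with an estimated correlation), with HMOX1 at 0.11 and the NADPH-producing enzyme PGD at 0.22. NK receptors did not pass (adjusted p = 0.396), though KLRB1 passed adjusted over the list alone and CD160 was at -0.21. Their median (0.023) and mean (-0.0042) differed in sign.

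**Figure D3:**
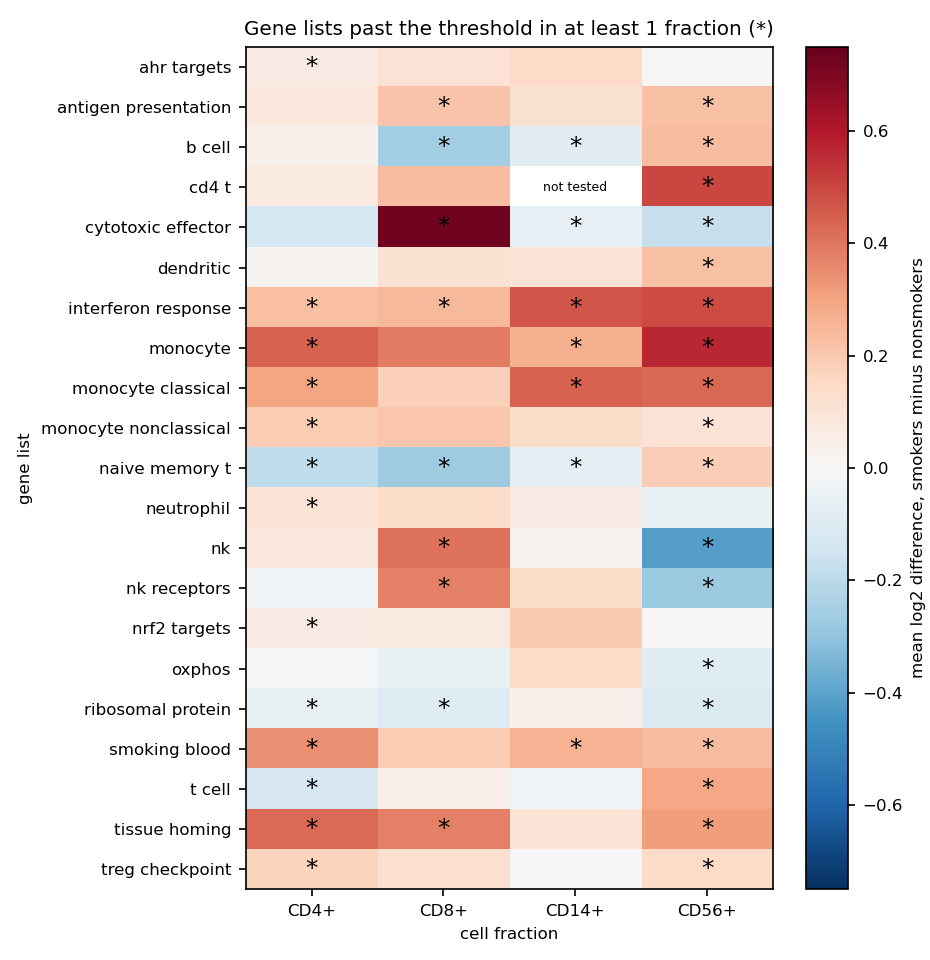
Mean log2 difference, smokers minus nonsmokers, of the gene lists (vertical axis) that passed camera at a preset correlation in at least 1 fraction (horizontal axis). An asterisk marks adjusted p under 0.05. Interferon genes are higher in every fraction (0.23 in CD4+, 0.24 in CD8+, 0.47 in CD14+ and 0.49 in CD56+ cells, the last 0.23 without series C), and cytotoxic genes are highest in CD8+ cells (0.72).

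The smoking difference of GPR15, SASH1 and FBP1 varied between fractions, for GPR15 in pairs with CD14+ cells alone, where it lay under the signal filter. GPR15 differed by 3.74 in CD4+, 2.49 in CD8+, 1.59 in CD56+ and -0.13 in CD14+ cells (SE 0.40 each, moderated F of limma, adjusted p = 0.000611), in donors with all 4 fractions. CD4+ exceeded CD14+ cells by 3.87 ± 0.57 (adjusted p = 4.74e-05) and CD8+ exceeded CD14+ cells by 2.62 ± 0.57 (adjusted p = 0.0477). The other pairs did not pass, CD4+ against CD8+ (1.26, adjusted p = 0.832) and CD56+ (2.15), CD8+ against CD56+ (0.90, adjusted p = 0.834) and CD14+ against CD56+ cells (-1.72, adjusted p = 0.113). SASH1 differed by 0.93 in CD14+, 0.20 in CD4+, -0.040 in CD8+ and 0.14 in CD56+ cells, each with SE 0.11 (adjusted p = 0.00103). The fit takes 1 residual spread per gene for all fractions, so an SE can be too small in the fraction where a gene varies most. In the fit of CD14+ cells alone the SE of SASH1 was 0.165. Its difference in CD14+ cells passed against CD8+ (adjusted p = 0.000527) and CD56+ cells (0.0415) but not against CD4+ cells (0.1). FBP1, a gluconeogenic enzyme of monocytes, differed by 0.66 in CD14+, 0.16 in CD4+, -0.088 in CD8+ and -0.036 in CD56+ cells, each with SE 0.099 (adjusted p = 0.015), and its CD14+ difference passed against CD8+ (adjusted p = 0.0105) and CD56+ cells (0.0415) but not against CD4+ cells (0.173). In CD14+ cells FBP1 averaged 8.499 against 8.05 in series A and 8.11 against 7.22 in series B. The cholesterol exporter ABCA1 came next (adjusted p = 0.055) with 0.63 in CD14+ cells and -0.065 in CD4+ cells, and LPAR6 followed (0.126). The guanine exchange factor DOCK4, NCOA1, LIN54, the kinase PRKCA and STRADB each had an adjusted p of 0.137. With the donor as a random block 11 genes passed, and with the donor as fixed terms 7. Without the donors of the 2 doubted CD8+ arrays GPR15 alone passed (adjusted p = 2.26e-06).

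**Figure D4:**
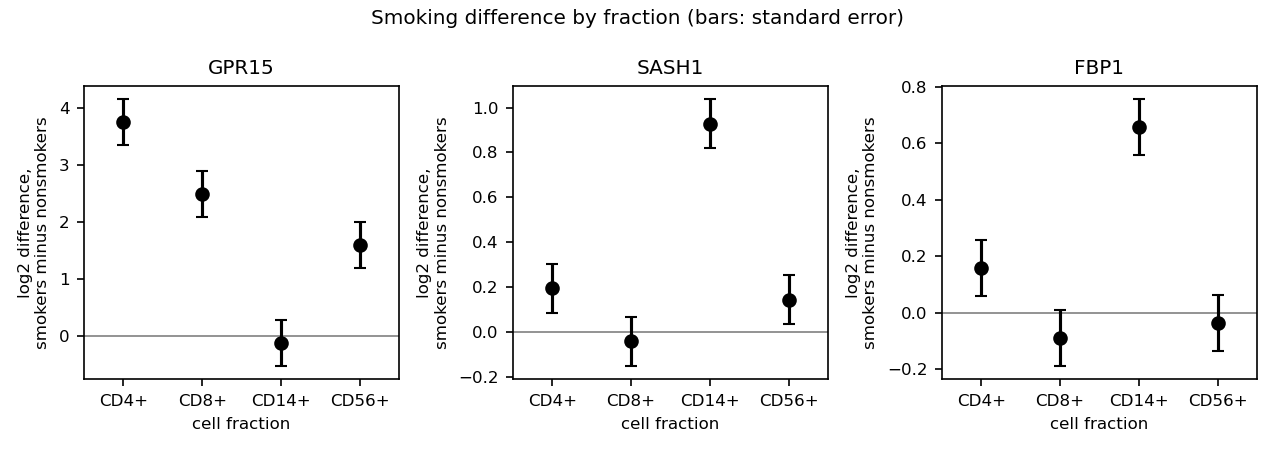
Smoking difference in log2 units (smokers minus nonsmokers, vertical axis) of the genes that varied between fractions (horizontal axis), with SE bars, in the 19 donors with all 4 fractions. Each SE comes from 1 residual spread per gene for all fractions. The estimate for GPR15 is largest in CD4+ cells (3.74), without passing against CD8+ or CD56+ cells, and those for SASH1 and FBP1 in CD14+ cells (0.93 and 0.66), without passing against CD4+ cells.

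Across genes, which are not independent replicates, the smoking differences of the fractions correlated weakly. Pearson's r was 0.325 between CD8+ and CD14+ cells, 0.165 between CD4+ and CD8+, 0.164 between CD8+ and CD56+, 0.112 between CD4+ and CD56+, 0.023 between CD4+ and CD14+ and -0.079 between CD14+ and CD56+ cells. The same donors enter each fraction, so reassigned smoking labels gave correlations as well. The highest of the 6 was reached by 15 of 100 assignments and the others by 64 to 95. With no donor shared between the fractions the mean r was 0.074 for CD8+ and CD14+ cells. Within a fraction, series A and B correlated at 0.371 in CD14+ cells, -0.011 in CD4+, -0.064 in CD8+ and -0.103 in CD56+ cells.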

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

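The tests of the array labels below were chosen after the mismatch was seen. Single arrays far from the rest of their group were sought by Dixon's ratio, the gap to the nearest array over the range, in groups of 9 or 10 arrays after centring each series. Chance flags about 1 in 20 values, or 6.7 of the 134 tested, and 20 were found.

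In CD8+ cells the labelled smoker with the lowest GPR15 (ratio 0.527) and the labelled nonsmoker with the highest (0.717) stood apart, as did the smoker with the lowest level of the granule protease GZMB (0.51). Both GPR15 values lie toward the other group. Donor-variable genes were used to ask whether arrays had been exchanged. The 2 CD8+ arrays that matched another donor came from opposite smoking groups, each matched the donor of the other, and the lower of the 2 correlations was 0.52, against -0.057 and -0.04 with their own donors. A swap of the 2 arrays between the groups is therefore a candidate explanation, and poor arrays without donor signal are argued against by the same 0.52, since they would match no donor. The files do not show whether the labels or the tubes were exchanged, so the deposited labels were kept. Without the 2 arrays the GPR15 difference was 3.19 instead of 2.49. No biological explanation was tested.

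Other CD8+ arrays stood apart in the transcripts of other cells. The highest monocyte marker mean among smokers (0.78) and the highest B cell marker mean among nonsmokers (0.761) each came from 1 array. T cell marker means had a low array in smokers (0.606) and in nonsmokers (0.503). Dendritic cell marker means had a low array in smokers (0.497) and a high one in nonsmokers (0.472).

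In CD4+ cells RCBTB2 had 1 high nonsmoker (0.565) and LCMT1-AS2 1 high smoker (0.598), and the B cell (0.774) and neutrophil (0.532) marker means each had 1 high smoker. In CD14+ cells SASH1 had 1 low smoker (0.608), and HCP5 (0.516) and XCR1 (0.578) had 1 high nonsmoker each. MIR1228 had 1 low nonsmoker (0.468). The platelet marker mean had 1 high smoker (0.602), the dendritic cell marker mean 1 high nonsmoker (0.498) and the monocyte marker mean 1 low nonsmoker (0.588). No cause was tested for these arrays.

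The smoking difference varied between fractions for GPR15 (moderated F of limma, adjusted p = 0.000611), SASH1 (0.00103) and FBP1 (0.015), which were picked out because the test addressed the difference between fractions itself. Of 100 assignments of smoking to donors within series, the real one included, 2 gave as many as the 3 genes found, and the highest other gave 3. Chance is argued against at that share, with no adjustment over the other tests of this kind.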

How the results depend on the processing

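The fits that left out the least correlated array or the 2 doubted CD8+ arrays, those combining series A and B by Stouffer's method, array weights with series A alone, cyclic loess, and lists without single arrays, GPR15 or series C were chosen after seeing the data. Of 2269 values of 149 gene results, 2175 kept their direction and side of the threshold, 33 no longer passed, 51 newly passed and 10 reversed. Only GPR15 in CD4+ cells and the 5 genes of donor means had passed in the main fits, and the 33 come from them. Most kept values belong to genes that did not pass either way, so the share kept does not measure how stable the calls are. Except where a group of arrays was removed, the cause was not tested.

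In CD4+ cells the count of 1 gene became 0 without the series term and in series B alone, where GPR15 differed by 3.66 and 4.50 instead of 3.74, and 3 with all fractions in 1 fit and the donor as replicate block (GPR15, LRRN3 and KLHDC1, the last named after its values were seen). In CD8+ cells the count of 0 became 1, GPR15, in series A alone, without the 2 doubted arrays and by Stouffer's method, 27 in series B alone, and 9 with the replicate block. In CD14+ cells the count of 0 became 611 with array weights, 568 with the replicate block, 5 with array weights in series A alone, 2 in series A alone (SASH1 and CLEC6A) 2 by Stouffer's method (SASH1 and HCP5) and 1, the noncoding SUCLA2-AS1, after cyclic loess within series. CLEC6A was named after its values were seen. In CD56+ cells the count of 0 became 1, GPR15, without series C and by Stouffer's method, and 8 with the replicate block. For donor means the count of 5 became 13 with array weights, 3 with no filter, with every probe set tested or with arrays centred on their medians, 2 with averaged probe sets, quantile normalization or series A alone, and 1 without the series term, with the marker covariate or in series B alone.

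The 3 genes that varied between fractions became 11 with the replicate block as random and 7 with it as fixed terms, 6 with arrays centred, and 1 without the series term or without the donors of the doubted arrays. The replicate block called the same 21, 10, 870 and 128 genes of CD4+, CD8+, CD14+ and CD56+ cells. With a difference over 2 log2 units these numbered 1 in CD4+, 3 in CD8+, 344 in CD14+ and 36 in CD56+ cells.

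Gene lists depended most on the correlation assumed. With an estimated correlation 0 passed in CD4+, CD8+ and CD14+ cells, and 1 in CD56+ cells and in donor means. In CD4+ cells 13 lists became 8 in series B alone and 8 without nonsmoker replicate 9, the least correlated array. In CD8+ cells 9 became 17 without the series term. In CD14+ cells 7 became 2 with the marker covariate, 11 with no filter, 3 without the series term and 3 without nonsmoker replicate 8. In CD56+ cells 18 became 11 in series A alone (7 higher and 4 lower) and 5 in series B alone (0 higher and 5 lower). With the marker covariate 15 passed, 3 higher and 12 lower, and 2 of the lists passed in the opposite direction. The covariate removes cell type signal by construction, but why lists turned was not tested. In donor means 11 became 20 in series A alone and 6 with the marker covariate. In either series alone (0 marker sets in A and 0 in B) 1 marker mean of CD56+ cells could not pass by itself at any size, as the permutations are too few for the adjustment. The CD4+ T cell marker mean was higher by 0.29 in A and 0.41 in B.

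With no donor shared, the correlation reversed to -0.041 between CD4+ and CD56+ cells and to -0.231 between CD8+ and CD56+ cells. Reversed genes were CLEC7A in CD56+ cells with the marker covariate (-0.074), CPVL in CD14+ cells with array weights in series A alone (-0.021), and PPP2CA in CD56+ cells without the series term (0.076). In series A alone they were ITGB1 in CD56+ cells (-0.0040), MYC (0.13) and NCR1 (-0.081) in CD8+ cells, RPL27 in CD4+ cells (0.073) and STAB1 in donor means (-0.0074). In series B alone LRRN3 reversed in CD8+ cells (-0.72), and with quantile normalization RPL27 in CD4+ cells (0.035). None of these 9 genes had passed over all genes in the pooled fit of its fraction, but MYC and NCR1 passed in CD8+ cells of series B alone. The B cell list of CD8+ cells reversed to 0.055 (from -0.26) without the nonsmoker array with the highest B cell marker mean. Signal over background limits genes near the floor, such as GPR15 in CD14+ cells.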

Other observations

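The scale test of GPR15 and the tests of CD14+ arrays by removal and by normalization were chosen after the results were seen. Of the 4 genes that rose in donor means beside GPR15, none passed with the marker covariate, and none varied between fractions in the moderated F. RCBTB2 was higher by 0.34 in CD4+, 0.35 in CD8+, 0.44 in CD14+ and 0.34 in CD56+ cells. CRYBG3 was higher by 0.46, 0.15, 0.66 and 0.27 in the same order. The transporter gene FLVCR2 (0.21, 0.13, 0.65 and 0.27) and the myeloid receptor gene LILRA2 (0.22, -0.013, 0.38 and 0.32) follow in the same order, and the estimates of all 4 were highest in CD14+ cells. KLRB1, which marks innate-like T cells and NK subsets, was lower in CD4+ (-0.41), CD8+ (-1.01) and CD56+ cells (-0.85), and in CD14+ cells it lay under the filter. Whether fewer such cells or less transcript per cell lies behind it was not tested.

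LPAR6 and RCBTB2 are neighbours in the GRCh38.p14 annotation, with 0 genes between them by start position. In donor means RCBTB2 rose by 0.36 and LPAR6 was higher by 0.24 without passing (adjusted p = 0.0983). In CD14+ cells they went apart, LPAR6 at -0.094 and RCBTB2 at 0.44. Over 19 donors, within smoking group and series, their mean levels correlated with Pearson's r = 0.698 (permutation p = 0.00034) and Spearman's rho = 0.753 (permutation p = 7e-04). This was the 1 correlation of the kind computed, so no adjustment applies. Without the 2 donors farthest from the median r was 0.718, and it was 0.768 in series A and 0.675 in series B. Levels that vary together between donors may make 1 difference appear as a pair in donor means, though not in CD14+ cells. No pairs of distant genes were computed for comparison, so r cannot tell neighbourhood from other variation between donors. Neither a shared genotype nor read-through was tested.

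Interferon genes were higher in smokers in every fraction, by a mean of 0.289 in the 19 donors. In CD56+ cells the mean was 0.221 in those donors and 0.492 with series C. Of 100 assignments of donors within series, the real one included, 10 gave as high a mean, and the highest other gave 0.382. A few donors with an interferon response who fell by chance in 1 group remain a candidate explanation.

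GPR15 in CD56+ cells of smokers reached 15.5% of its CD4+ level in series A, where T cell markers reached 4.82% to 105% (median 22.5%). In series B it reached 2.39%, under the lowest marker (2.73%). Every marker left room for the whole signal in series B, but the markers disagreed in series A. There 8 of 15 reached a higher share than GPR15. The CD4+ T cell markers CCR4 (4.82%), ANKRD55 (4.89%), CTLA4 (5.4%), TSHZ2 (5.94%) and ICOS (10.7%) reached a lower one. Carry-over of T cells and expression by NK cells therefore cannot be told apart, and the sort was not repeated. A larger T cell share in smokers stays open. With the T cell marker mean as a covariate the difference was 1.557 ± 0.335 log2 units instead of 1.97 ± 0.34 (adjusted p = 0.61 with the covariate, where its p was 0.000145). It stayed over 2 SE, but the covariate cannot decide. It averages 15 markers, among them CD2, which reached 105% of its CD4+ level in CD56+ cells of series A, so it follows the share of CD4+ T cells loosely. The series scale is argued against, since the difference was 1.829 ± 0.247 in A alone and 1.321 ± 0.334 in B alone.

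The broad CD14+ difference at unadjusted p had 1912 genes higher in smokers and 874 lower, where chance gives 382 each way. For the higher genes, 1 array is argued against as the whole cause, since 1618 were called without the least correlated array, 1513 of them among the 1912. For the lower genes it was left open, as the 688 called lay under the bound set for arguing against it. They were still above the 383 that chance gives on average. Of the 688, 596 were among the 874, so most of the lower calls did not need that array. The scale of the arrays stays open for both. After cyclic loess, which evens the arrays of a series at each signal level, 809 were higher (695 of the 1912) and 673 lower (382 of the 874). These are fewer but still above the 382 each way that chance gives on average. Reassigned labels gave up to 3271 genes in the main fit, and the loess counts were not set against such labels. The count of higher genes alone would have argued against the scale. That most genes should be called again was required only after these counts were seen, so the test was left open. Centring and quantile normalization shift the median difference upward (0.103 and 0.0482 instead of 0.00494) and decide neither part. Array weights, with no rescaling, gave 2385 higher and 2709 lower. With the marker covariate 772 were higher and 355 lower, the latter under the 382 that chance gives. The covariate includes monocyte markers, and what it removed was not tested. T and NK cells carried over into the nonsmokers' fraction are argued against, as far as the deposited values can be read as log2. Each marker, background included, caps the share, so the lowest T and the lowest NK marker were taken. They allowed at most 2.94% in series A and 0.192% in B, where the median rise of the monocyte markers needed 15.1%. That rise was 0.237 log2 units, and 0.103 without nonsmoker replicate 8, for which no needed share was computed. The median marker shares in series A were higher, at 8.34% (T) and 12% (NK). B cells and platelets were not covered by that test. The correlation of the series (0.371) was reached by 5 of 100 assignments (highest other 0.512) and the 2786 genes by 5 (highest other 3271), so chance assignment may account for the pattern, and smoking stays open beside it.

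Smoking was reassigned to donors within series in 99 other ways, and the counts below include the real assignment. In CD4+ cells the 1 gene was matched by 3 of 100 (highest other 3), the 626 genes at unadjusted p under 0.05 by 52 (2819) and the 13 lists by 5 (17). Chance is argued against for the gene, at that share, and not for the lists. In CD8+ cells the 0 genes were matched by 100 (highest other 6), the 949 at unadjusted p by 14 (3944) and the 9 lists by 33 (13), while the 27 genes of series B alone were matched by 1, the real one (9). In CD14+ cells the 0 genes were matched by 100 (highest other 0), the 7 lists by 13 (11) and the 611 genes with array weights by 3 (1458). In CD56+ cells the 0 genes were matched by 100 (highest other 1), the 1141 at unadjusted p by 16 (2605) and the 18 lists by 1, the real one (16). In donor means the 5 genes were matched by 2 (highest other 104), the 1069 at unadjusted p by 20 (3024) and the 11 lists by 18 (17). Chance is argued against for the counts matched by fewer than 5, at the share given and with no adjustment over these tests. The CD8+ arrays of series B behind the 27 genes include the 2 doubted ones. Assignments that called several times the real count, such as the 104 genes in donor means, point to a structure of the samples or to genes that vary together, and these were not told apart by a test. With fractions shuffled within donors, the 21, 10, 870 and 128 genes of CD4+, CD8+, CD14+ and CD56+ cells were each matched by the real arrangement alone, 1 of 100, and the highest other was 0.

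Transcript clusters without a single gene symbol, unnamed or with several symbols, gave 0 past the threshold by limma in each fraction. In CD14+ cells 2220 of 17493 had an unadjusted p under 0.05, in CD4+ 749 of 17656, in CD8+ 674 of 17663 and in CD56+ cells 1448 of 17763.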
